A study of Homo sapiens with 18 samples.

How the data were processed

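RNA from 18 samples was measured on the human Affymetrix U133 Plus 2.0 array, which carries 54675 probe sets. The samples came from 2 human embryonic stem cell lines, VUB01 and SA01, each taken as undifferentiated cells (hES), as neural precursor cells (NPC) and as the mesodermal cells that the labels call MSC or MPC (mesodermal precursor cells, MSC here), with 3 arrays for each of the 6 combinations. Per the labels, 100 ng of total RNA per sample went through 2 rounds of amplification and labelling. The labels number the arrays of a combination as biological replicates and say nothing more about separate cultures, so the p-values measure the spread between these arrays, part of which may be technical. NPC were harvested after 21 days in vitro on a mouse MS5 stromal layer and sorted with an antibody against NCAM, and both the positive and the negative fraction were collected. The labels do not say which fraction was arrayed, so NCAM1 was treated as no finding. The hES were grown on mouse STO cells. Whether mouse transcripts from these cells or from the MS5 layer reached the probe sets was not tested. The protocol text for the MSC is cut short in the labels.

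The deposited values are linear intensities made by the authors, per the labels and the submitters' processing notes, which name GCRMA without a version. As usually run, GCRMA subtracts a background that depends on probe sequence, quantile-normalises the arrays and summarises the probes of a probe set, so probe sets with no target end at a floor and a change in total RNA per cell cannot be seen. Whether it was run with its usual settings is not given in the sources used here. Array dates and a genome build are not given in the sources used here, so no batch could be tested and no coordinates are printed. If arrays were run by cell type or by line, that batch and the biology cannot be told apart.

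Values were analysed as log2 of the intensity plus a pseudocount of 1. Differences are therefore on the log2(intensity + 1) scale, which understates the change of dim genes. Probe sets were named through the platform table. Of all probe sets, 62 were controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 were unnamed, and none was named from an entry with several symbols. Of those with 1 symbol, 41037 matched the reference gene table (GRCh38.p14, used for names only) and 0 symbols needed updating. XIST, TSIX and Y-linked genes, 77 probe sets, were left out of every step. A gene was represented by its probe set of highest mean over all arrays, which gave 19732 genes.

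The background limit was the 95th percentile of 135 probe sets for olfactory receptors, genes that these cells are not known to use, and lay at 3.65 on the log2 scale, an intensity of 11.6. A gene was tested if at least 3 arrays exceeded this limit, which kept 12602 genes and left out 7130. Of the tested genes, 8401 had several probe sets. For a called gene with several measured probe sets, another probe set was called in the opposite direction for 54 genes in NPC against hES, 63 in MSC against hES and 81 in NPC against MSC. Where every array of a cell type was at or below the limit, the difference is given as at least the gap between the mean of the brighter cell type and the limit. The same was done between lines where every array of 1 line in a cell type was at or below it. Where only some arrays were at or below the limit, the difference of means is given as it is, and it depends on the floor of the values.

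limma (version 3.58.1, in R 4.3.3) was fitted to all 18 arrays with 1 mean for each of the 6 combinations, leaving 12 residual degrees of freedom. Cell types were compared by contrasts averaged over the lines with equal weight, lines were compared within each cell type, and an interaction contrast tested whether a cell type difference differed between lines. Standard errors and p-values came from eBayes with default settings, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called when its adjusted p was under 0.05 and its difference at least 1 on the log2 scale. All tests were two-sided. Errors after ± are standard errors of the difference unless SD is stated.

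Before the data were examined, 28 gene lists were fixed, together with the comparisons, the alternatives and the rule for named genes. They cover pluripotency, neural, glial, neural crest, mesenchymal, mesodermal, endodermal, trophoblast and epithelial markers, regional identity, the cell cycle, metabolism, interferon response, signalling pathways, imprinted genes and chromatin. Each list was tested with camera from limma at its preset correlation between genes of 0.01, against all other tested genes, where it had at least 5 tested members. This held for 27 lists, which were adjusted together in each comparison. Members were also adjusted over the list alone. With a correlation estimated from the data in place of the preset one, no list passed in any comparison.

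Named genes were, for each comparison of cell types, the 8 with the largest increase and the 8 with the largest decrease among called genes of the same sign in both lines that exceeded the limit in both cell types, and the 4 with the largest lower bound in each direction. Added to these were up to 4 called members of each list by size with its brightest member that was not called, 4 genes per direction in each comparison of lines, and the 5 leading genes highest in each cell type. Provisional locus names were passed over. Pseudogenes and near-identical copies are reported as uncertain, because a probe set can bind more than 1 of them.

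The code was tested on simulated data. With 200 changed genes among 12602, the comparison of NPC with hES recovered 25.4% of changes of 1 log2, 91% of changes of 2 and 93.9% of changes of 3, with 4 false calls. The comparison of lines in hES recovered 17.9%, 82.1% and 80.3% with 9 false calls. camera found 10 of 10 shifted lists and 0 of 100 unchanged lists, but the genes were simulated as independent. The simulation therefore did not test false calls of lists whose genes vary together. Precision is limited by the number of arrays. Alternatives covered scaling, the filter on dim genes, the choice of probe sets, the spread model, the thresholds, each line alone, a replicate block, the correlation used by camera and leaving out each array.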

Results

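Gene expression was measured in 18 arrays from the human embryonic stem cell lines VUB01 and SA01, with 6 arrays for each of 3 cell types, undifferentiated cells (hES), neural precursor cells (NPC) and mesodermal precursor cells (MSC), and 3 arrays per line within each. The comparisons that the design implies ask which genes distinguish the cell types from each other, which are shared by both derivatives, and which depend on the line. On average 11422 ± 106 genes (SD, n = 6) exceeded the background limit in hES, 11569 ± 82.8 in NPC and 11213 ± 111 in MSC. Replicate arrays of a combination correlated across genes with r between 0.931 and 0.984. The ratio of the 3' to the 5' control probe set, which rises when RNA is degraded or amplified from short products, differed by cell type. For ACTB it was 13.1 ± 5.1 (SD, n = 6) in hES, 28.4 ± 3.6 in NPC and 12.6 ± 2.1 in MSC. For GAPDH it was 2.03 ± 0.08, 2.41 ± 0.28 and 1.53 ± 0.14. For ACTB every NPC array (24.4 to 34.6) lay above every hES array (9.18 to 22.9) and every MSC array (10.2 to 15.8). For GAPDH the NPC range (1.89 to 2.62) overlapped that of hES (1.91 to 2.15). Every MSC array (1.33 to 1.72) lay below both of these GAPDH ranges. Such a difference in 3' bias and the cell type cannot be told apart in any comparison of cell types. Its part in the calls was not tested. The arrays of VUB01 and SA01 called replicates carry no statement of separate cultures beyond that name.

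A principal component analysis of the tested genes placed the arrays by cell type. The first component held 57.0% of the variance and set MSC apart, and the second held 19.5% and parted hES from NPC. On this second component hES SA01 replicate 3 lay at -4.36 and NPC SA01 replicate 2 at 20.9, between the other hES arrays (-75.3 to -49.4) and the other NPC arrays (50.2 to 88.4). NANOG, a transcription factor of pluripotent cells, had an intensity of 1751 in NPC SA01 replicate 2, against 7.81 to 183 in the other NPC arrays and 3553 to 8683 in hES. LHX2, a transcription factor of the embryonic forebrain, had an intensity of 252 in hES SA01 replicate 3, against 5.51 to 26.0 in the other hES arrays.

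**Figure D1:**
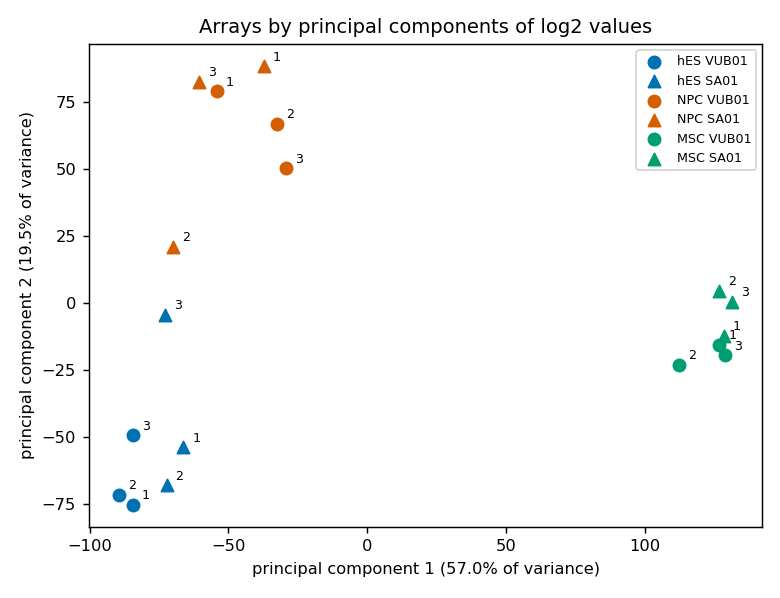
First and second principal components of the log2(intensity + 1) values of the tested genes, 1 point per array, coloured by cell type, with the marker shape giving the line and the number the replicate. The first component (57.0% of the variance) separates MSC, and hES SA01 replicate 3 and NPC SA01 replicate 2 lie between the other hES and NPC arrays on the second (19.5%).

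NPC were first compared with hES. LHX2 was higher in NPC by 8.39 ± 0.75 log2 (SE, n = 6 arrays per cell type, limma adjusted p = 6.09e-06). PAX6, which directs eye and forebrain formation, was higher by 6.80 ± 0.60 (limma adjusted p = 5.99e-06). SIX3, also a regulator of the forebrain and eye, rose by 6.28 ± 0.94, SOX5 by 5.96 ± 0.61, LIX1 by 5.90 ± 0.68 and DACH1 by 5.77 ± 0.60. The imprinted gene DLK1, a membrane protein related to NOTCH ligands, rose by 5.89 ± 0.82 and the matrix protein gene POSTN by 6.58 ± 0.96. Of the 6 hES arrays, 4 were at or below the background limit for LHX2, SIX3, SOX5 and POSTN, 5 for LIX1 and 3 for DACH1, so these differences depend on the floor of the values. PAX6 lay just above the limit, at 3.68 to 3.80, in hES VUB01 replicates 1 and 2 and hES SA01 replicates 1 and 2. Its difference thus also depends on values near the floor. POSTN reached 9.25 and 8.85 in hES SA01 replicates 1 and 3. SIX6, an eye field gene, GABRP, SCUBE1 and KCNJ13 were at background in hES and higher in NPC by at least 2.98, 4.61, 3.36 and 2.64 log2. Each of these 12 genes was higher in 6 of 6 NPC arrays than the hES mean.

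Among the genes lower in NPC, LEFTY1, an inhibitor of NODAL signalling, fell by 7.62 ± 0.86 log2 (SE, n = 6, limma adjusted p = 2.03e-05), the neuropeptide gene GAL fell by 6.47 ± 0.63 and NANOG fell by 6.18 ± 0.88 (limma adjusted p = 9.74e-05). LCK, a kinase known from T cells, fell by 5.58 ± 0.55. Of the 6 NPC arrays, 5 were at or below the limit for LEFTY1, 4 for GAL, 3 for LCK and 1 for NANOG. HLA-DPB2, POU5F1P4 and POU5F1P3 gave differences of -6.87, -6.01 and -5.93, which are uncertain as gene identities because these are pseudogenes whose probe sets can bind related transcripts. DPPA5, LINC00458, CBR3 and PPP1R16B did not exceed background in NPC, with differences of at least -2.20, -3.01, -2.26 and -2.61.

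Of the 22 tested pluripotency genes, 18 fell in NPC, 0 rose and 4 were not called (camera adjusted p = 2.7e-11, and adjusted p = 0.318 with an estimated correlation), with 18 also when adjusted over the list alone. GDF3, a TGF beta family ligand, fell by 5.32 ± 0.37, while the RNA-binding protein gene LIN28A differed by only -0.64 ± 0.16, at means of 13.97 in hES and 13.33 in NPC. Of 25 neural progenitor genes, 23 rose and 2 were not called (camera adjusted p = 3.17e-11, and adjusted p = 0.318 with an estimated correlation), with 23 adjusted over the list alone. NES, the brightest member not called, differed by 0.66 ± 0.43. The mean of the pluripotency list was 8.77 log2 in NPC SA01 replicate 2 against 6.66 to 7.03 in the other NPC arrays, and that of the neural progenitor list was 7.53 in hES SA01 replicate 3 against 4.66 to 5.53 in the other hES arrays. Neural crest genes were higher in NPC for 9 of 12 members, with 3 not called (camera adjusted p = 0.00928, adjusted p = 0.513 with an estimated correlation), and 9 rose and 1 fell when adjusted over the list alone. TFAP2B and TFAP2A rose by 5.03 ± 0.93 and 4.80 ± 0.83, and SNAI2, which promotes the release of cells from epithelia, by 3.96 ± 0.75, while ETS1 differed by -0.70 ± 0.27. The mean of this list was 8.15 in hES SA01 replicate 3 against 4.86 to 5.82 in the other hES arrays. It was 5.83 in NPC VUB01 replicate 3 against 7.82 to 9.22 in the other NPC arrays. The call of this list was lost without the probe sets marked as shared between transcripts (adjusted p = 0.0734 by camera) and in SA01 alone (0.0634).

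**Figure D2:**
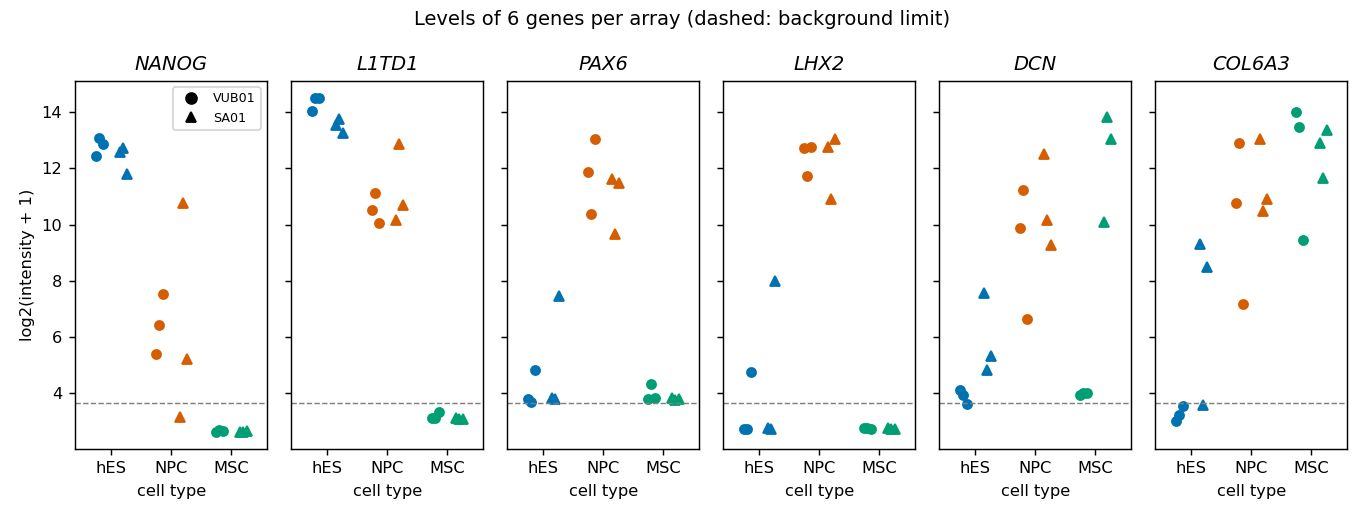
Intensity of NANOG, L1TD1, PAX6, LHX2, DCN and COL6A3 on each array as log2(intensity + 1), with circles for VUB01, triangles for SA01 and a dashed line at the background limit of 3.65. NANOG is high in all hES arrays, at background in MSC and at 10.78 in NPC SA01 replicate 2, and PAX6 and LHX2 are high in NPC and raised in hES SA01 replicate 3.

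Signalling genes and matrix genes also differed between NPC and hES. Of 17 NOTCH pathway genes, 11 rose and 1 fell in NPC, with 5 not called and the same counts adjusted over the list alone (camera adjusted p = 0.000141, adjusted p = 0.318 with an estimated correlation). The ligand gene DLL1 rose by 5.21 ± 0.67 and the target HES5, at background in hES, by at least 2.20, whereas another target, HEY2, fell by 3.60 ± 0.44. Of 24 WNT genes, 13 rose, 1 fell and 10 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.000373, adjusted p = 0.398 with an estimated correlation). Among them were LEF1 (4.77 ± 0.74), a nuclear effector of the pathway, and FRZB (3.94 ± 0.88), a secreted WNT antagonist. TGF beta and BMP genes rose for 12 and fell for 1 of 25, with the same counts adjusted over the list alone (camera adjusted p = 0.00281, adjusted p = 0.406 with an estimated correlation). They included the receptor BMPR1B (3.79 ± 0.42) and the BMP antagonist GREM1 (2.93 ± 0.44), and the list was not called in SA01 alone (camera adjusted p = 0.172). Extracellular matrix genes rose for 20 of 31 members and fell for 0 (camera adjusted p = 4.73e-07, adjusted p = 0.398 with an estimated correlation), and 22 rose when adjusted over the list alone. COL6A3 rose by 5.71 ± 1.11, DCN by 5.06 ± 0.81 and LUM by 4.86 ± 1.13, while FN1 differed by 0.86 ± 0.45. In SA01 alone, COL6A3 and LUM were no longer called, at 4.36 and 3.09. The hES arrays were uneven, with a list mean of 8.97 in SA01 replicate 1 and 8.69 in SA01 replicate 3 against 6.61 to 7.53 in the others. In these 2 arrays the intensity of LUM was 1571 and 1197, against 6.74 to 27.1 in the other hES arrays, and that of COL6A3 was 626 and 360, against 6.88 to 11.0. In NPC VUB01 replicate 3 the intensities of COL6A3 and DCN were 144 and 98.7, the lowest of the NPC arrays.

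Some genes of antigen presentation and of epithelial junctions were lower in NPC than in hES. Of 19 genes of MHC class I and the interferon response, 8 fell, 0 rose and 11 were not called, with 8 adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.575 with an estimated correlation). This call was lost without NPC VUB01 replicate 1 (camera adjusted p = 0.0558). PSMB8, a subunit of the immunoproteasome, fell by 4.32 ± 0.48, and the peptide transporter genes TAP2 and TAP1 fell by 3.06 ± 0.41 and 2.70 ± 0.32, while B2M differed by 0.08 ± 0.22. Of 24 epithelial genes, 13 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00338, adjusted p = 0.513 with an estimated correlation). The claudin genes CLDN7 and CLDN6 of tight junctions fell by 2.91 ± 0.44 and 2.87 ± 0.48. The epithelial call was lost in VUB01 alone (camera adjusted p = 0.0586) and with no filter on dim genes (0.0546), and that of the MHC list in VUB01 alone (0.0586), with no filter (0.222) and without the probe sets shared between transcripts (0.688). Imprinted genes rose for 6 of 17, and fell for 1 only when adjusted over the list alone (camera adjusted p = 0.00338, adjusted p = 0.318 with an estimated correlation), among them PLAGL1 (3.37 ± 0.66) and PEG10 (1.57 ± 0.31). Both DNMT3B, a DNA methyltransferase, and PHC1, a Polycomb protein, fell, by 2.82 ± 0.38 and 2.74 ± 0.34.

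In all, limma called 2914 genes between NPC and hES, 1598 higher and 1316 lower in NPC, which is 23.1% of the tested genes. Of these, 2895 had the same sign in both lines and 1970 differed by at least 1 log2 in both, and the differences in the 2 lines correlated across genes with r = 0.810. Without hES SA01 replicate 3 and NPC SA01 replicate 2, left out together after the data were seen, the count was 3560. Camera called 10 of 27 lists, 7 higher and 3 lower, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). In SA01 alone the number of called genes was 1882.

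MSC were compared with hES in the same way. LOX, an enzyme that cross-links collagen, was higher in MSC by 9.45 ± 0.76 log2 (SE, n = 6 arrays per cell type, limma adjusted p = 5.09e-08). COL8A1 rose by 9.41 ± 1.00, the proteoglycan gene SRGN by 9.33 ± 0.76, GREM1 by 9.17 ± 0.44 (limma adjusted p = 2.59e-10), IGFBP7 by 9.11 ± 0.73 and NNMT by 9.01 ± 0.62. PRRX1, a transcription factor of limb and craniofacial mesenchyme, rose by 8.34 ± 0.77 and ARID5B by 8.30 ± 0.45. CEMIP, ARSJ, LINC01279 and MIR100HG were at background in hES and rose by at least 6.99, 6.86, 6.57 and 6.32. TRIM71, a regulator of early development and a target of the let-7 microRNAs, fell by 10.27 ± 0.16 (limma adjusted p = 1.06e-15) and the epithelial adhesion gene EPCAM fell by 9.74 ± 0.48. Of the 6 hES arrays, 5 were at or below the limit for SRGN and PRRX1, 4 for COL8A1 and ARID5B, 3 for LOX and NNMT and 2 for GREM1. Of the 6 MSC arrays, 5 were for TRIM71 and 1 for EPCAM. Each of these genes moved in the stated direction in 6 of 6 MSC arrays against the hES mean.

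LIN28A, L1TD1 and CDH1 (E-cadherin) did not exceed background in MSC, with differences of at least -10.32, -10.29 and -9.48. All 22 pluripotency genes fell in MSC, also adjusted over the list alone (camera adjusted p = 3.46e-10, adjusted p = 0.146 with an estimated correlation), with differences of at least -8.94 for NANOG and -8.85 for SOX2. Of 31 extracellular matrix genes, 29 rose and 0 fell (camera adjusted p = 2.94e-13, adjusted p = 0.146 with an estimated correlation). Of 23 mesenchymal surface and cytoskeleton genes, 21 rose and 0 fell (camera adjusted p = 4.89e-10, adjusted p = 0.051 with an estimated correlation). The counts of both lists were the same adjusted over the list alone. NT5E and CD44, surface proteins used to identify mesenchymal stromal cells, rose by 7.67 ± 0.15 and 7.38 ± 0.69, whereas THY1, another such marker, differed by 0.63 ± 0.43 from a mean of 9.54 ± 0.86 (SD, n = 6) in hES. FBN1 (fibrillin) rose by 7.48 ± 0.37, POSTN by 8.12 ± 0.96 and COL6A3 by 7.30 ± 1.11. Of 24 epithelial genes, 18 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000235, adjusted p = 0.402 with an estimated correlation), with a difference of -7.50 ± 0.48 for CLDN6.

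All 29 cell cycle genes fell in MSC, also adjusted over the list alone (camera adjusted p = 9.3e-06, adjusted p = 0.563 with an estimated correlation). The mitotic checkpoint genes BUB1 and TTK fell by 4.62 ± 0.58 and 4.32 ± 0.58, and the replication gene MCM5 fell by 4.15 ± 0.45. The mean of this list ranged widely between MSC arrays, from 5.82 log2 in MSC VUB01 replicate 1 to 10.0 in MSC VUB01 replicate 2. Of 12 genes of p53 and cell cycle inhibition, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000567, adjusted p = 0.4 with an estimated correlation). The inhibitor genes CDKN1A and CDKN2A rose by 6.16 ± 0.59 and 4.88 ± 0.21, and CDKN2B, at background in hES, by at least 6.21. MHC class I and interferon genes rose for 10 and fell for 2 of 19, with 11 higher adjusted over the list alone (camera adjusted p = 0.000554, adjusted p = 0.4 with an estimated correlation). They were led by B2M (2.78 ± 0.22) and NLRC5 (at least 1.68), while IFITM1 fell by 3.59 ± 0.63.

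Of 25 TGF beta and BMP genes, 14 rose and 5 fell in MSC, also adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.4 with an estimated correlation). The ligand genes TGFB2 and INHBA rose by 7.67 ± 0.45 and 6.90 ± 0.48, and the receptor gene ACVR2B fell by 5.46 ± 0.19. HOX genes, which mark position along the body axis, rose for 6 of 14 and fell for 0, also adjusted over the list alone (camera adjusted p = 0.00186, adjusted p = 0.402 with an estimated correlation). Camera did not call them in VUB01 alone (adjusted p = 0.178). Of 18 genes of DNA methylation and Polycomb, 10 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00887, adjusted p = 0.146 with an estimated correlation). The differences were -7.81 ± 0.38 for DNMT3B and -5.39 ± 0.39 for TET1, which oxidises methylated cytosine. The call was lost without the probe sets shared between transcripts (camera adjusted p = 0.134). FGF genes fell for 12 and rose for 3 of 20, also adjusted over the list alone (camera adjusted p = 0.0473, adjusted p = 0.146 with an estimated correlation), with FGFR2 lower by a difference of -5.55 ± 0.55. This FGF call is near its threshold and passed in 19 of 31 alternatives and leave-outs (camera adjusted p from 0.011 to 0.134). It was lost without hES VUB01 replicate 1 (0.0516), hES SA01 replicate 2 (0.0532), NPC VUB01 replicate 1 (0.0507), 2 (0.0626) or 3 (0.0508), MSC VUB01 replicate 1 (0.0529) or 2 (0.0749) or MSC SA01 replicate 2 (0.0565). It was also lost with a filter at a log2 value of 6 (0.0511), a replicate block (0.0572), SA01 alone (0.118) and without the probe sets shared between transcripts (0.134). Immediate early genes, which respond quickly to stimulation, rose for 7 and fell for 3 of 16, also adjusted over the list alone (camera adjusted p = 0.0287, adjusted p = 0.563 with an estimated correlation). IER3 rose by 4.73 ± 0.48 and DUSP1 by 3.41 ± 0.32. This call was lost without MSC VUB01 replicate 1 (camera adjusted p = 0.0529), with a range of 0.0192 to 0.178 over the alternatives at the preset correlation. It was also lost with equal array medians (0.0629), no filter on dim genes (0.0858), without the probe sets shared between transcripts (0.178) and without the 2 arrays left out together after the data were seen (0.0507).

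In all, limma called 5629 genes between MSC and hES, 2107 higher and 3522 lower in MSC, 44.7% of those tested, of which 5595 had the same sign in both lines. The median of all tested genes was itself shifted by -0.25 log2, so the split between higher and lower depends on scaling. With equal array medians (median shift 0.07) the split was 2749 higher and 2650 lower, and with quantile normalisation (-0.01) it was 2583 and 2812. Camera called 12 of 27 lists, 7 higher and 5 lower, and 0 with an estimated correlation (5 at an unadjusted p under 0.05).

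**Figure D3:**
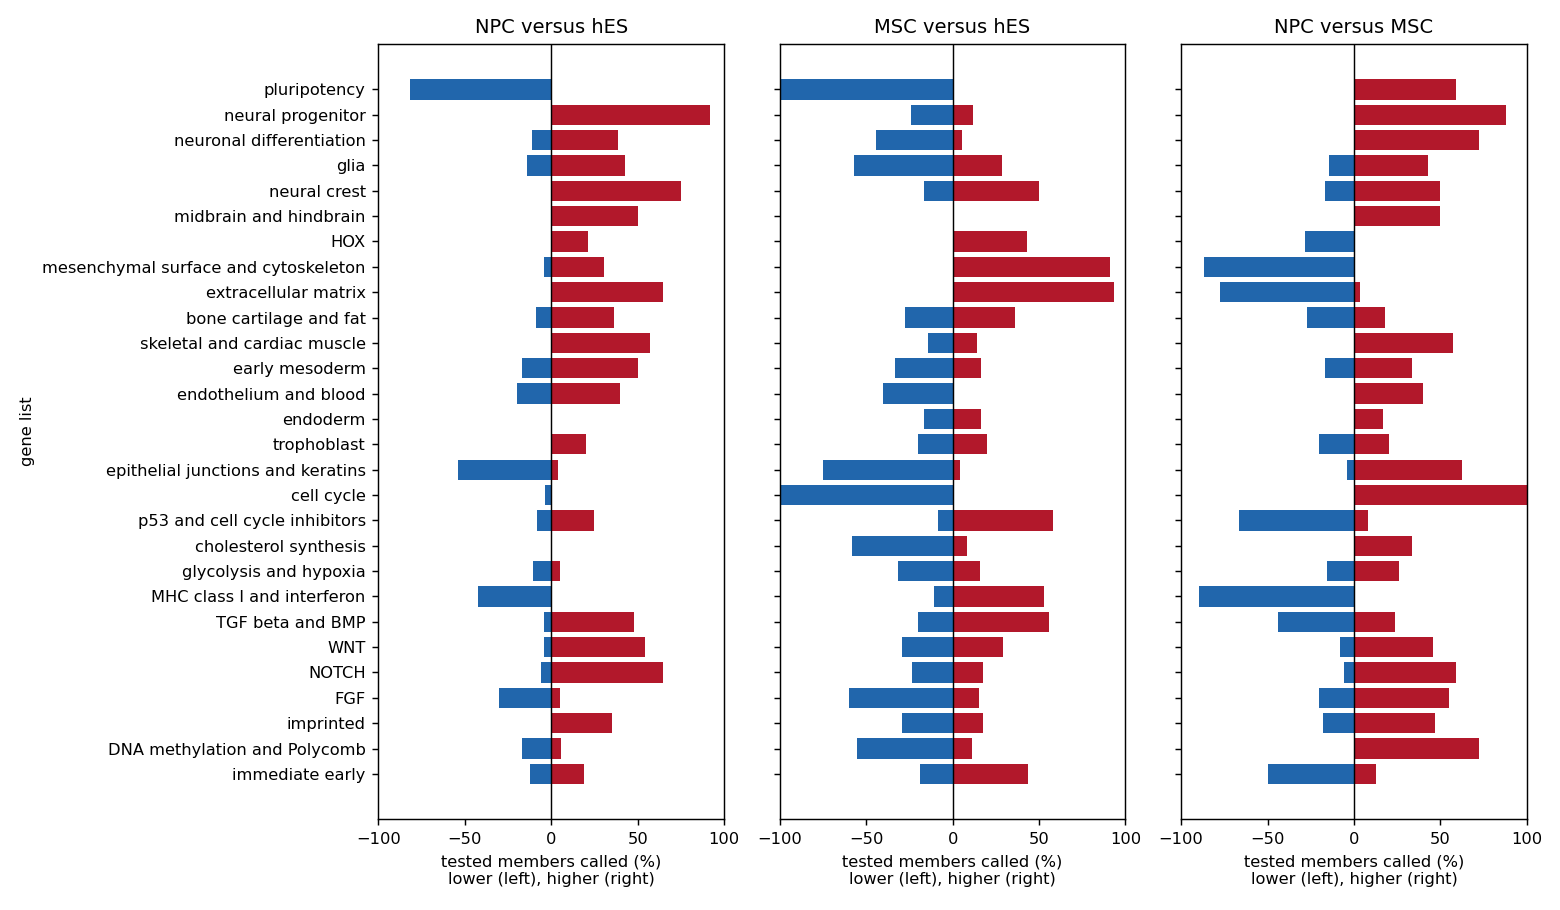
Percent of the tested members of each of the 28 gene lists that were called higher (to the right) or lower (to the left) in NPC against hES, MSC against hES and NPC against MSC. Pluripotency genes are lower in NPC (18 of 22) and in MSC (22 of 22), and all 29 cell cycle genes are lower in MSC than in both other cell types.

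NPC and MSC were then compared directly. PRTG, an adhesion protein of the early neural tube, was higher in NPC by 9.77 ± 0.82 log2 (SE, n = 6 arrays per cell type, limma adjusted p = 1.18e-07). TRIM71 was higher by 9.29 ± 0.16, NELL2 by 8.94 ± 0.33, PTPRZ1 by 8.66 ± 0.39 and LIN28B by 8.06 ± 0.66. SFRP2 (a secreted WNT modulator), LIN28A, FZD5 (a WNT receptor) and OTX2 (a head-patterning factor) did not exceed background in MSC and were higher in NPC by at least 10.04, 9.68, 9.58 and 8.82. SRGN fell by 8.25 ± 0.76 in NPC relative to MSC, INHBA fell by 7.96 ± 0.48, THBS2 fell by 7.82 ± 0.42 and the smooth muscle actin gene ACTG2 fell by 7.54 ± 0.47. CD274, the ligand of the immune receptor PD-1, fell by 7.10 ± 0.44, and the interferon-inducible GBP1 and GBP3, at background in NPC, were lower by at least -5.50 and -5.67. Of the 6 MSC arrays, 5 were at or below the limit for PRTG, TRIM71 and PTPRZ1, 3 for LIN28B and 1 for NELL2. Of the 6 NPC arrays, 5 were for CD274, 4 for SRGN and 1 for INHBA. Each of these genes differed in the stated direction in 6 of 6 NPC arrays against the MSC mean.

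All 29 cell cycle genes were higher in NPC than in MSC, also adjusted over the list alone (camera adjusted p = 8.42e-06, adjusted p = 0.555 with an estimated correlation). Of 19 MHC class I and interferon genes, 17 were lower in NPC and 0 higher, also adjusted over the list alone (camera adjusted p = 1.04e-07, adjusted p = 0.237 with an estimated correlation), with differences of -3.84 for TAP2, -3.49 for TAP1 and -3.01 for PSMB8. Neural progenitor genes rose for 22 of 25 (camera adjusted p = 3.62e-06, adjusted p = 0.375 with an estimated correlation). Neuronal genes rose for 13 of 18 (camera adjusted p = 0.00747, adjusted p = 0.358 with an estimated correlation), and neither list had a member that fell. LHX2 and FABP7, at background in MSC, were higher by at least 8.68 and 7.25, MAP2, a microtubule protein of dendrites, by 7.18 ± 0.70 and DCX, a protein of migrating neurons, by at least 4.04. Pluripotency genes were higher in NPC for 13 of 22 and lower for 0 (camera adjusted p = 0.000375, adjusted p = 0.491 with an estimated correlation), with SOX2 higher by at least 8.69 and L1TD1 by at least 7.25. The counts of these 4 lists were the same adjusted over the list alone. The neuronal call was lost in SA01 alone (camera adjusted p = 0.0544).

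Mesenchymal surface and cytoskeleton genes fell for 20 of 23 in NPC relative to MSC (camera adjusted p = 6.74e-09, adjusted p = 0.0657 with an estimated correlation). Extracellular matrix genes fell for 24 and rose for 1 of 31 (camera adjusted p = 1.42e-08, adjusted p = 0.34 with an estimated correlation). NT5E, at background in NPC, was lower by at least -7.38, CD44 fell by 7.19 ± 0.69 and COL2A1, the main collagen of cartilage and also a gene of the notochord and neural plate, was higher in NPC by at least 5.87. Genes of p53 and cell cycle inhibition fell for 8 and rose for 1 of 12 (camera adjusted p = 0.000602, adjusted p = 0.358 with an estimated correlation). DNA methylation and Polycomb genes rose for 13 of 18 and fell for 0 (camera adjusted p = 0.000461, adjusted p = 0.0814 with an estimated correlation). The counts of these 4 lists did not change adjusted over the list alone. NOTCH genes rose for 10 and fell for 1 of 17, also adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.54 with an estimated correlation), but not with a filter at a log2 value of 6 (camera adjusted p = 0.0808). Epithelial genes rose for 15 and fell for 1 of 24, with 16 higher adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.547 with an estimated correlation), and this call was lost in SA01 alone (camera adjusted p = 0.358). Immediate early genes fell for 8 and rose for 2 of 16 in NPC relative to MSC, also adjusted over the list alone (camera adjusted p = 0.0348, adjusted p = 0.555 with an estimated correlation). The differences were -4.49 ± 0.48 for IER3 and -3.10 ± 0.32 for DUSP1. The call was lost without NPC VUB01 replicate 1 (camera adjusted p = 0.0515), NPC SA01 replicate 3 (0.0582) or MSC VUB01 replicate 1 (0.0718). It was also lost with equal array medians (0.0901), quantile normalisation (0.056), no filter on dim genes (0.48), VUB01 alone (0.053) and without the probe sets shared between transcripts (0.265).

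In all, limma called 5143 genes between NPC and MSC, 3334 higher and 1809 lower in NPC, 40.8% of those tested. The median of all tested genes was shifted by 0.22, and the split changed to 2343 higher and 2664 lower with equal array medians (median shift -0.17) and to 2612 and 2488 with quantile normalisation (-0.06). Of the called genes, 5100 had the same sign in both lines. Camera called 12 of 27 lists, 7 higher and 5 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05).

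Genes called in the same direction in both derivatives numbered 1595, with 653 higher and 942 lower in NPC and in MSC than in hES, and 250 genes moved in opposite directions. The 942 lower genes are those highest in hES, led by LEFTY1, GAL and NANOG among well-identified genes, and 807 genes were highest in NPC, led by LHX2, PAX6, SIX3, LIX1 and DLK1, and 1416 in MSC, led by SRGN, NT5E, ARSJ, MMP1 and LINC01279. These orders use differences of means and depend on the floor of the values. ARSJ and LINC01279 were at background in hES and had mean intensities of 6.79 and 7.34 in NPC. The comparisons of NPC and of MSC with hES use the same hES arrays. All arrays, those of hES included, were simulated without change around the hES means, and the simulated comparisons shared 0 calls on average. Without a change few calls can arise, so this count does not show how far shared arrays raise the overlap. Independent lists of these sizes would share 267.2 higher and 367.8 lower genes. The differences of the 2 derivatives correlated across genes with r = 0.458 against 0.495 for unchanged simulated groups, and their covariance was 0.923 against 0.0476 simulated. With the hES arrays split by line so that no array was shared, VUB01 NPC and SA01 MSC shared 607 higher and 1015 lower genes (237.9 and 425.5 for independent lists), and SA01 NPC and VUB01 MSC shared 324 and 510 (191.7 and 236.8).

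Between the lines, 14 genes differed in the same direction in all 3 cell types. PEG3, an imprinted gene expressed from the paternal copy, was at background in every SA01 array. It was lower in SA01 than in VUB01 by a difference of at least -7.86 log2 in hES (n = 3 arrays per line, limma adjusted p = 4.12e-06), -9.79 in NPC and -3.70 in MSC. NAP1L5, another imprinted gene, was higher in SA01 by 4.99 ± 0.33, 6.15 ± 0.33 and 6.43 ± 0.33 in hES, NPC and MSC (SE, n = 3). Its VUB01 means of 3.64, 3.73 and 3.85 lay at or next to the background limit. CAT, the gene of catalase, was higher by 4.38 ± 0.63 in hES and, with VUB01 at background, by at least 5.67 in NPC and 6.72 in MSC. ZNF558, a zinc finger gene, was at background in SA01 and lower there by differences of at least -3.75, -5.06 and -3.09. The other 10 were ASTE1, LOC389831, MEIS3P1 (a pseudogene, uncertain), QPCT, RAPGEF1, RBM46, TSPYL5, WARS2, WDR90 and ZXDA. For LOC389831, RAPGEF1, WARS2 and WDR90 another measured probe set did not differ this way in all 3 cell types.

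**Figure D4:**
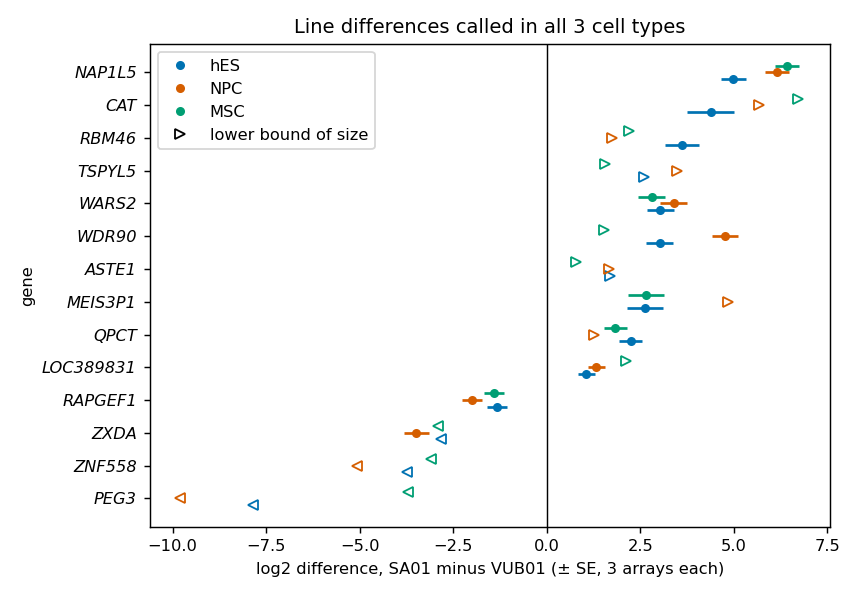
Difference between lines, SA01 minus VUB01 on the log2(intensity + 1) scale, for the 14 genes called in hES, NPC and MSC, as filled points with standard errors from limma (3 arrays per line in each cell type) or, for the 22 of 42 differences with every array of 1 line at background, as open triangles at the lower bound. PEG3, ZNF558, ZXDA and RAPGEF1 lie below 0 in each cell type and the other 10 genes above 0.

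In hES, limma called 101 genes between lines, 53 higher and 48 lower in SA01. NR2F1, a nuclear receptor, was higher in SA01 by 5.93 ± 0.77 and DNAJC15 by 5.48 ± 0.85, and SNHG17 and CALCA were lower by differences of -2.72 ± 0.43 and -2.72 ± 0.41. The mean of CALCA in SA01 hES was 3.69, next to the background limit. The count was 37 without hES VUB01 replicate 2 and 47 without hES SA01 replicate 1. Of the 3 SA01 arrays, replicate 3 is the array with raised neural genes, and without it the count was 105, with differences of 5.74 for NR2F1 and 5.21 for DNAJC15. SA01 replicates 1 and 3 also had extracellular matrix list means of 8.97 and 8.69, against 6.61 to 7.53 in the other hES arrays. Of the 31 matrix genes, limma called 1 higher in SA01 hES, and 12 had an unadjusted p under 0.05. In NPC, 93 genes were called, 49 higher and 44 lower, with TUSC1 higher by 6.75 ± 0.73 and the imprinted gene NNAT by 4.82 ± 0.45, and ALDH1A3, an enzyme of retinoic acid synthesis, lower by a difference of -3.92 ± 0.70. The mean of TUSC1 in VUB01 NPC was 2.67, below the limit. The call of ALDH1A3 was lost without NPC SA01 replicate 3 (-3.90), and the count was 164 without NPC VUB01 replicate 1. With equal array medians the splits were 71 higher and 45 lower in hES and 58 and 63 in NPC. Fits to the 6 arrays of 1 cell type alone gave 15 genes in hES and 23 in NPC, and array weights gave 840 in hES.

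In MSC the lines differed at 703 genes, 367 higher and 336 lower in SA01. CLDN11, a claudin, was higher by 8.77 ± 0.70 (SE, n = 3 arrays per line, limma adjusted p = 3.7e-06), the matrix proteoglycan gene DCN by 8.35 ± 1.15 and DIO2, which activates thyroid hormone, by 7.07 ± 0.69. The mean of DCN in VUB01 MSC was 3.98, close to the background limit, against 12.33 in SA01 MSC, and that of CLDN11 in VUB01 MSC was 3.39, below it. IL6, a cytokine, was lower in SA01 by a difference of -4.32 ± 0.40, with a mean of 3.06 in SA01 MSC, below the background limit, and PNMA2 by -4.40 ± 0.59, with a mean of 3.74 there. Of 14 HOX genes, 8 were higher in SA01 MSC and 0 lower, 9 adjusted over the list alone. HOXC10 and HOXD10, chosen after the values were seen, were among them, at background in VUB01 MSC and higher in SA01 by at least 0.98 and 3.84. The difference of HOXD10 between NPC and MSC, which averaged below 0, was 0.17 in VUB01 alone. Of 31 extracellular matrix genes, 4 were higher and 0 lower, 5 adjusted over the list alone, and of 17 imprinted genes 5 were higher and 1 lower, also adjusted over the list alone. The count of 703 dropped to 326 without MSC SA01 replicate 2 and to 381 without MSC SA01 replicate 3, and with equal array medians the split was 400 higher and 233 lower. The 6 MSC arrays alone gave 145 genes and array weights 1188.

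The line differences of the cell types overlapped. Cells of hES and NPC shared 11 genes higher and 5 lower in SA01 (0.206 and 0.168 for independent lists), hES and MSC 13 and 9 (1.54 and 1.28) and NPC and MSC 24 and 7 (1.43 and 1.17). There were 3 genes in opposite directions in the last pair and 0 in the others. The cell types do not share arrays, but the single fit gave a gene the same standard error in all 3. The calls of the 3 cell types are therefore not independent. Because genes are not independent, the Fisher exact p-values of 1.94e-17, 2.74e-08 and 1.37e-19 describe these lists only.

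A test of the difference itself found 24 genes whose change from hES to NPC differed between lines, 133 for MSC against hES and 143 for NPC against MSC. The line difference, the SA01 change minus the VUB01 change, was above 0 for 10 and below 0 for 14 of these genes in the first comparison, for 85 and 48 in the second and for 42 and 101 in the third. C1S, a protease of the complement system, had means of 10.90 in SA01 MSC and 4.81 in VUB01 MSC against 6.13 and 6.84 in hES. Its line difference was 6.79 ± 0.91 (SE, n = 3 arrays per combination, limma adjusted p = 0.00133), and DPP4, a surface peptidase, had a line difference of 5.70 ± 0.98. PDPN (podoplanin), with a line difference of 6.21 ± 1.11, had a mean of 3.95 in VUB01 MSC against 10.53 in VUB01 hES, while the SA01 means were 9.48 and 9.85. KRT8, a keratin, was higher in NPC than in MSC in VUB01 (11.53 and 8.64) and lower in SA01 (9.47 and 12.63), a line difference of -6.04 ± 0.94 (limma adjusted p = 0.00424). Array weights gave 139, 886 and 340 genes for the 3 comparisons, and a replicate block gave 14, 86 and 75. The counts also moved with single arrays, from 24 to 6 without hES VUB01 replicate 2, 9 without NPC SA01 replicate 3, 13 without hES SA01 replicate 1 and 47 without hES VUB01 replicate 3. The count of 133 became 81, 76, 73, 82, 68 and 76 without hES VUB01 replicate 1 or 2, hES SA01 replicate 1 or 2 or MSC SA01 replicate 2 or 3, and 251 without MSC SA01 replicate 1. The count of 143 became 65, 60 and 79 without MSC SA01 replicate 2 or 3 or NPC SA01 replicate 3, and 253 without MSC SA01 replicate 1. With equal array medians the splits were 5 above and 16 below 0 for NPC against hES and 25 and 116 for NPC against MSC.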

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

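The comparison of lines and the tests of explanations were set before their results were seen, except that the estimator of mixed signal, its comparison with the other arrays of a cell type, the test of a wrong label against every array of the other cell type and the division of splits by whole lines were chosen after first values were seen. Dixon's test of single values was not run, since the groups hold 3 arrays each.

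What set these results apart is a difference between the lines in the change from 1 cell type to another, tested with limma as an interaction. Values are the SA01 change minus the VUB01 change on the log2 scale. For NPC against hES, 24 genes differed in this way. This difference was above 0 for H1-1 (3.87), FAM124A (2.98) and ZNF470 (1.63), and below 0 for ANXA1 (-8.36), NR2F1 (-6.11), BHLHE40 (-5.93) and MEIS1 (-5.27). Single arrays ended these calls in some of the 18 leave-outs, in 2 for H1-1 (3.62 to 3.89), 11 for FAM124A (2.67 to 3.09), 13 for ZNF470 (1.45 to 1.72) and 4 for ANXA1 (-8.42 to -7.31). They ended in 11 for NR2F1 (-6.55 to -5.43), 4 for BHLHE40 (-6.33 to -5.45) and 12 for MEIS1 (-5.66 to -4.55).

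For MSC against hES, 133 genes differed, with values above 0 for C1S (6.79), CLDN11 (6.47), PDPN (6.21) and DPP4 (5.70) and below 0 for ZFHX3 (-4.75), PNMA2 (-4.21), ANTXR2 (-4.06) and OPCML (-3.89). Leaving out an array ended the call in 4 of 18 cases for PNMA2 (-4.29 to -3.69), 6 for ANTXR2 (-3.97 to -3.51) and 12 for OPCML (-4.19 to -3.20). For NPC against MSC, 143 genes differed, among them PNMA2 (4.97), ACTN3 (4.09), ITGA6 (3.95) and EMB (3.77) above 0 and TCIM (-7.39), PRSS35 (-6.73), CLSTN2 (-6.05) and KRT8 (-6.04) below 0. The call of EMB ended in 16 of 18 leave-outs (3.27 to 4.05) and that of CLSTN2 in 10 (-6.33 to -4.88).

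Other splits of the arrays by line within each cell type were counted. For the 24 genes of NPC against hES, 9 of 100 splits gave as many, with a highest other count of 240, and for the 143 genes of NPC against MSC it was 9 of 100, with 553. For the 133 genes of MSC against hES, 4 of 100 splits gave as many (highest other 243), a share under 0.05 but close to it. With 100 splits drawn and 3 comparisons tested, this share does not exclude chance. Counts of several times the real one point to a structure of the samples. In each comparison 26 of the other splits kept the lines whole in 1 cell type, and such a split carries that line difference into the interaction. They gave 7 of the 8 other counts as large for NPC against hES, 3 of 3 for MSC against hES and 8 of 8 for NPC against MSC. The highest was 240 with lines whole in hES and 27 with lines whole in NPC in the first comparison. It was 243 with MSC whole and 22 with hES whole in the second, and 553 with MSC whole and 23 with NPC whole in the third. The 73 splits that mixed the lines in both cell types gave at most 35, 4 and 84 genes, as many as the real split in 1, 0 and 0 cases. The 9 of 100 therefore does not decide on chance for NPC against hES or NPC against MSC. For MSC against hES, 3 of the 13 other splits with MSC lines whole gave as many, so with the line difference of MSC kept, chance in hES is not excluded.

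The array of NPC SA01 replicate 2 carried signal of genes highest in hES. Its share of hES signal was 0.397 (95% bootstrap interval 0.377 to 0.422) from 1080 genes highest in hES and 0.583 (0.554 to 0.619) from 941 genes highest in NPC, a difference of 0.186, and the other NPC arrays gave -0.054 to 0.00175 and -0.497 to 0.424. Undifferentiated cells in the sample may have contributed, but the wide spread of the second share among the other NPC arrays (SD 0.48) keeps this open, and with the first estimator the shares were 0.356 and 0.66, further apart than the limit of 0.2 set for a mixture. For a wrong label, the larger share, 0.583, lies between the limits of 0.5 and 0.8 set before, which left it undecided. In the 6 hES arrays, however, the same shares were at least 0.572 and 0.695, above the upper ends here by at least 0.0756. Both lowest values came from hES SA01 replicate 3, which itself stands apart. The intervals resample genes within 1 array, so this gap is not measured against the spread between arrays. The intensities of LHX2 and PAX6 were 1936 and 816, against 5.51 to 252 and 11.8 to 172 in hES. This argues against a sample of hES like those measured. A mixed sample that was also mislabelled and a less complete differentiation were not tested.

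The array of hES SA01 replicate 3 showed the opposite, with a share of NPC signal of 0.305 (0.281 to 0.325) from 922 genes highest in NPC and 0.428 (0.408 to 0.454) from 972 genes highest in hES, a difference of 0.123. The other hES arrays gave -0.0465 to 0.0183 and -0.328 to 0.181 (SD 0.202). Differentiating cells in the sample may have contributed, but the spread of the second share keeps this open, and with the first estimator the shares were 0.257 and 0.481, further apart than the limit of 0.2. For a wrong label, both shares, the larger being 0.428, lie with their intervals under the limit of 0.5 that was set before, which argues against it. In the 6 NPC arrays the same shares were at least 0.417 and 0.603, above the upper ends here by at least 0.0918. Both lowest values came from NPC SA01 replicate 2. This check and the one for that array thus compare the same 2 arrays and are not separate evidence. The intervals here also resample genes, not arrays. NANOG had an intensity of 3553, against 7.81 to 1751 in NPC. A mixed sample that was also mislabelled and spontaneous differentiation were not tested.

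Extracellular matrix genes were higher in NPC than in hES, and MSC-like cells within the NPC samples were tested as a source. The 50 MSC genes outside the list were the most abundant of those called highest in MSC and at background in hES. They reached a median of 0.00613 (0.00172 to 0.0145) of their MSC level in NPC. The 20 matrix genes, which were those called higher in NPC, reached 0.154 (0.0708 to 0.23). Both choices use NPC levels and lower the ratio of 0.0397 (0.0126 to 0.15), and the intervals resample genes, not arrays. The size of the ratio is therefore not a measure of evidence. A call of highest in MSC still left room for a share such as 0.154. The low share of the 50 genes therefore argues against cells with the profile of the measured MSC as the source. Other cells that make matrix, transcripts of the mouse MS5 layer and matrix expression by NPC themselves stay open and were not tested.

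The line differences shared by all 3 cell types may reflect a sequence variant under a probe set. Of 7 shared genes with another measured probe set, 3 differed the same way in that probe set as well (CAT, NAP1L5 and PEG3), which is 42.9% (exact 95% interval 9.9 to 81.6). For LOC389831, RAPGEF1, WARS2 and WDR90 the other measured probe set did not differ this way by at least 1 log2 in all 3 cell types. The remaining shared genes had no other measured probe set. These genes are too few to decide, and a difference in genotype or imprinting between the lines stays open as untested.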

How the results depend on the processing

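Leaving out hES SA01 replicate 3 and NPC SA01 replicate 2 together, or these and NPC VUB01 replicate 3, was chosen after the data were seen, and the other alternatives were set before. Of 271 counts under other settings, 217 lay within 1.5 times the reported count and 54 did not, and of 288 counts with 1 array left out, 268 did and 20 did not. For named genes, 7663 of 8148 values kept their side of the threshold, 402 became weaker, 75 stronger and 8 reversed. With 1 array left out the numbers were 8116, 261, 41 and 0 of 8418. A reversal was counted only where at least 1 of the 2 fits called the gene. Values called in neither fit count as kept, even where their sign changed. For lists, counted by the same rule, 999 of 1092 were kept, with 60 weaker and 33 stronger. With 1 array left out, 1426 of 1449 were kept, with 13 weaker and 10 stronger. Where a result changed, the cause was not tested unless stated.

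Counts are given for lines in hES, NPC and MSC and for interactions in NPC against hES, MSC against hES and NPC against MSC, in that order where all are listed. Thresholds moved counts by construction. By adjusted p alone, NPC against hES gave 5845, NPC against MSC 8062, both derivatives 3357, and highest in hES, NPC and MSC 2176, 1531 and 2237. At an adjusted p under 0.01, lines gave 48, 48 and 296 and interactions 8, 50 and 52. A test against a difference of 1 (treat) gave 716, 3310 and 2784 for the cell types, 19, 17 and 101 for lines, 2, 31 and 37 for interactions, 376 for both derivatives, and 217, 212 and 758 for genes highest in hES, NPC and MSC.

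With every probe set on its own, lines gave 214, 150 and 1085 and interactions 39, 234 and 219, with more features tested. With the mean of all probe sets of a gene, NPC against hES gave 1935, both derivatives 1040 and highest in NPC 524. A filter at a log2 value of 6 gave 66 for lines in hES and 7 for NPC against hES between lines. Array weights gave 840 for lines in hES, 1188 in MSC, and 139, 886 and 340 for interactions. A replicate block of line and number gave 14, 86 and 75 for interactions, but arrays sharing a number were not more alike than others (r from -0.204 to 0.321 over 18 pairs, own number best in 5). Fits with only the 6 arrays of the cell type gave 15, 23 and 145 for lines, with fewer samples. SA01 alone gave 1882 for NPC against hES, 804 for both derivatives and 492 for highest in hES. Camera with an estimated correlation called 0, 0 and 0 lists, with 4, 5 and 3 at an unadjusted p under 0.05. Leaving out 3 arrays gave 46 for NPC against hES between lines.

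With 1 array left out, lines ranged from 37 (without hES VUB01 replicate 2) to 146 in hES, 62 to 164 (without NPC VUB01 replicate 1) in NPC and 326 (without MSC SA01 replicate 2) to 751 in MSC, with 47 without hES SA01 replicate 1 and 381 without MSC SA01 replicate 3. Interactions ranged from 6 (without hES VUB01 replicate 2) to 47 (without hES VUB01 replicate 3), 68 (without MSC SA01 replicate 2) to 251 and 60 (without MSC SA01 replicate 3) to 253 (both highest values without MSC SA01 replicate 1). The cell type counts ranged from 2601 to 3329, 5552 to 5703 and 4899 to 5270.

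Reversed were TGFBR1 for NPC against MSC without x and s probe sets (3.49, another probe set), HOXD10 (0.17) and KRT18 (1.07) for NPC against MSC in VUB01 alone. In SA01 alone, reversed were BMP4 (-0.039) and PLK2 (-0.27) for NPC against hES, PEG3 (0.00075) for MSC against hES, and GATA3 (-0.51) and PEG3 (-0.046) for NPC against MSC, where PEG3 was at background in SA01. Dim genes are limited by the background, since differences near 3.65 log2 are compressed.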

Other observations

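The summaries by array, the unnamed probe sets and the lists in splits with 0 called genes were looked at after the data were seen, and the splits of the arrays were set before. Neuronal genes were in part higher in NPC than in hES, with 7 of 18 higher, 2 lower and 9 not called (camera adjusted p = 0.066). MAP2 rose by 5.06 ± 0.70 log2 (SE, n = 6 arrays per cell type) and STMN2, a regulator of microtubules in growing axons, by 4.82 ± 0.62, each in 6 of 6 arrays, while CRMP1 differed by -0.50 ± 0.23. Within the FGF list, where 1 gene rose and 6 fell of 20 (camera adjusted p = 0.456, with a median of 0.03 and a mean of -0.35), FGF9 rose by 5.65 ± 0.45 and FGF4, a growth factor of pluripotent cells, fell by 4.89 ± 0.45.

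In MSC, metabolic genes moved both ways. Of 12 cholesterol synthesis genes, 7 fell and 1 rose against hES (camera adjusted p = 0.0975), with HMGCS1 down by a difference of -1.86 ± 0.19. Of 19 glycolysis and hypoxia genes, 3 rose and 6 fell (camera adjusted p = 0.897, with a median of -0.18, a mean of -0.22 and a test direction upward), where the glucose transporter gene SLC2A3 fell by 3.51 ± 0.38 and NDRG1 rose by 3.30 ± 0.42. The mean of the 29 cell cycle genes was 5.82 in MSC VUB01 replicate 1 and 10.0 in MSC VUB01 replicate 2, with 7.43 to 8.04 in the other MSC arrays, against 10.67 to 11.14 in hES and 10.38 to 10.87 in NPC.

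Of the remaining lists for NPC against hES, glia genes rose for 3 and fell for 1 of 7, HOX rose for 3 of 14 (camera adjusted p = 0.0654), and mesenchymal surface and cytoskeleton 7 up and 1 down of 23. Bone, cartilage and fat genes had 4 up and 1 down of 11 and muscle 4 up of 7 (camera adjusted p = 0.0634). Early mesoderm had 3 up and 1 down of 6, endothelium and blood 2 up and 1 down of 5, and trophoblast 1 up of 5. Cell cycle genes fell for 1 of 29 and p53 and inhibitor genes rose for 3 and fell for 1 of 12. Adjusted over the list alone these were 0 of 29, and 2 up and 1 down of 12, and early mesoderm had 3 up and 2 down. The calls of MCM5, GADD45A and MDM2 in these lists were lost in 8, 15 and 4 of 18 leave-outs. Glycolysis had 1 up and 2 down of 19, DNA methylation and Polycomb 1 up and 3 down of 18 (median 0.24, mean -0.08), and immediate early 3 up and 2 down of 16. By limma, 0 of 6 endoderm genes and 0 of 12 cholesterol genes were called, with 1 and 3 at an unadjusted p under 0.05. The midbrain and hindbrain list had only 2 tested genes, 1 of them higher, and was not tested.

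For MSC against hES, neural progenitor genes rose for 3 and fell for 6 of 25, neuronal 1 up and 8 down of 18, and glia 2 up and 4 down of 7. Neural crest had 6 up and 2 down of 12, bone, cartilage and fat 4 up and 3 down of 11, and muscle 1 up and 1 down of 7. Early mesoderm had 1 up and 2 down of 6, endothelium and blood 2 down of 5, and endoderm 1 up and 1 down of 6. Trophoblast had 1 up and 1 down of 5, WNT 7 up and 7 down of 24, NOTCH 3 up and 4 down of 17 and imprinted genes 3 up and 5 down of 17. Adjusted over the list alone, neural progenitor genes had 3 up and 5 down and endoderm genes 1 up and 0 down. Of the 2 midbrain and hindbrain genes limma called 0, with 0 at an unadjusted p under 0.05. The median, the mean and the test differed in sign for muscle, early mesoderm, endoderm, glycolysis, WNT, NOTCH and imprinted genes, and camera called none of these.

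For NPC against MSC, glia genes rose for 3 and fell for 1 of 7, neural crest 6 up and 2 down of 12, and HOX 4 down of 14 (camera adjusted p = 0.0607). Bone, cartilage and fat had 2 up and 3 down of 11, and muscle 4 up of 7. Early mesoderm had 2 up and 1 down of 6, endothelium and blood 2 up of 5, endoderm 1 up of 6 and trophoblast 1 up and 1 down of 5. Cholesterol genes had 4 up of 12, glycolysis 5 up and 3 down of 19, and TGF beta and BMP 6 up and 11 down of 25. WNT had 11 up and 2 down of 24, FGF 11 up and 4 down of 20, imprinted 8 up and 3 down of 17, and midbrain and hindbrain 1 up of 2. Signs differed between median, mean and test for bone, early mesoderm, trophoblast and glycolysis, which camera did not call.

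Between lines in MSC, 5 of 24 epithelial genes were higher in SA01 and 0 lower, 6 and 1 adjusted over the list alone, with CDH3 higher by 3.99 ± 0.66 (SE, n = 3 arrays per line). Of 4640 tested probe sets without a gene name, limma called 921 higher and 315 lower in NPC than in hES, 482 and 1040 in MSC than in hES, and 1568 and 406 in NPC than in MSC.

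Other splits of the arrays within lines were counted for each result. For genes called between cell types, 1 of 100 splits, the real one, gave as many in each comparison. This excludes chance in how these arrays were grouped. Whether the replicates were separate cultures is not given, so the splits cannot exclude chance differences between cultures. Nor can such splits exclude the 3' bias, which set the NPC arrays apart for ACTB and the MSC arrays apart for GAPDH. The real count was 2914 against a highest other count of 1782 for NPC and hES, 5629 against 3335 for MSC and hES and 5143 against 3374 for NPC and MSC. The same held for both derivatives (1595 against 134) and for genes highest in hES (942 against 73), NPC (807 against 653) and MSC (1416 against 646). For lists, chance is not excluded for NPC against hES, where 43 of 100 splits gave at least 10 lists (highest 18), or for NPC against MSC, where 23 of 100 gave at least 12 (highest 16). For MSC against hES 4 of 100 gave at least 12 (highest 13), a share under 0.05 but close to it. With 100 splits drawn and 3 comparisons tested, this share does not exclude chance either. Splits with 0 called genes still gave up to 18, 13 and 16 lists in the 3 comparisons, with medians of 8, 6 and 7.5, so the number of lists says little about the size of a change. Between lines the 10 splits are too few for a share under 0.05, with 101 genes against a highest other of 7 in hES, 93 against 61 in NPC and 703 against 25 in MSC.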
